A study of Mus musculus with 4 samples.

How the data were processed

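RNA sequencing was used to profile insulin-positive cells obtained by reprogramming primary mouse gallbladder cells. The cells came from C57BL/6-background mice aged 8 weeks that carry MIP-GFP, a green fluorescent protein under an Ins1 promoter. Per the labels' protocols, the cells received the transcription factors Pdx1, Neurog3 (Ngn3), Mafa and PAX6 together with compounds that are not named there, over 10 days. Reporter-positive cells were then isolated by fluorescence-activated cell sorting, and TruSeq v2 libraries were made from total RNA. The samples form 1 group, rGBC2, with 4 libraries numbered 1 to 4 in the labels. The labels do not say whether the 4 came from separate animals, cultures or reprogramming experiments, so every p-value rests on these 4 libraries alone, and part of their spread may be technical.

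The authors deposited 1 table of RPKM values (reads scaled to transcript length and to the mapped reads of the library), rounded to 2 decimals, with 20377 genes, each under 1 gene symbol and 1 RefSeq transcript identifier. Per the submitters' processing notes, CASAVA 1.8.2 and Bowtie were used and the genome build is mm9. The counting program, its strand setting and its treatment of reads with several matches are not given in the sources used here. Coordinates are those of the deposited table. The table also has 6 per-sample columns whose names match no sample of this series, and they were not used, so no comparison with unreprogrammed cells or with native beta cells was made. The reference annotation at hand belongs to another build and served only for transcript lengths, base composition and shared sequence, matched by RefSeq identifier for 19992 genes (98.1%). The delivered factors and the cells' own copies of the same genes cannot be separated in gene-level values.

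RPKM values hold no read totals. An estimate was made from 993 olfactory receptor genes that span under 1100 bases, for which the RPKM of 1 read was fitted to the low values of each library. All the low values then lay within 0.0051 RPKM of a whole number of reads, although the step had been fitted to those same 14 to 32 values per library and the rounding is coarse for 1 read. This fit was chosen after a simpler estimate had left many values between whole reads. The estimated depths were 24.1 M, 22.1 M, 24.6 M and 32.8 M reads for replicates 1 to 4. At these depths 3 reads on a transcript of 1 kilobase correspond to 0.125, 0.135, 0.122 and 0.0915 RPKM, and these floors cover counting error only. The comparison of each pair of libraries with sampling noise used reads estimated from these depths and the transcript lengths, for genes with at least 20 reads in the pair.

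The test across genes, the list values, the differences and the SDs on a log2 scale use log2(RPKM + 1), which compresses differences between low genes, except that the ratios of the reprogramming factors use log2(RPKM). Means and SDs in RPKM, ratios and shares use RPKM itself, and list medians in RPKM are converted back from the log2 scale. With a single group, the test across genes asked which genes lay above or below 1 RPKM. It used limma 3.58.1 in R 4.3.3 with moderated variances and a mean-variance trend, so its p-values also draw on the spread of other genes of like level. The test was two-sided, with Benjamini-Hochberg adjustment over the 16919 genes not at 0 in every library and a threshold of 0.05. The 3458 genes listed at 0 in all 4 libraries were not tested. On simulated data built from 5102 real genes near the threshold, 3.82% of 4902 genes set at 1 RPKM had an unadjusted p under 0.05, and none passed adjustment. Of 100 genes set at 4 RPKM 53% passed, and of 100 genes set at 2 RPKM 0% passed, although 74% had an unadjusted p under 0.05.

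Before the data were examined, 26 gene lists with 346 genes were fixed, of which 344 had a row in the table used here. For each list the median over all measured members was taken per library. Its level was placed among 10000 random lists of the same size drawn from genes not at 0 in every library. The spread between libraries, as the median SD of the members, was placed among 10000 random lists matched on mean level. On simulated lists, 100% of 200 planted lists from the most abundant genes and 7.5% of 200 random lists reached percentile 95. These percentiles describe the 4 libraries and are not p-values. Where a gene of a list was at 0 in any library, the values of each library are given in place of a mean and its error, since Gapdh is also at 0 in 1 library.

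7 planned differences between lists or genes within each library were tested with an exact two-sided sign-flip permutation test over the 4 libraries. The smallest p it can give with 4 libraries is 0.125, printed rounded in the report, so none can pass 0.05, and the values, their SD and the number of libraries with each direction carry the comparison. RPKM is scaled to transcript length, but base composition and the gene model still affect a ratio between genes.

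The genes named were fixed by rule: all reprogramming factors, insulin genes and islet hormones, the 3 most abundant members of every other list and the first 2 members below 1 RPKM, the 15 most abundant genes, and the 10 genes with the largest SD of log2(RPKM + 1) among those with a mean of at least 5 RPKM. Neurod1, Isl1, Pcsk1, Pcsk2, Kdm5d, Arhgap6 and the ribosomal protein genes Rps18, Rps27 and Rpl28 were named after their values were seen. Some genes that meet the rule are not reported here. Alternatives were a pseudocount of 0.1, a filter at 0.1 RPKM, a threshold of 0.5 RPKM, 2 rescalings between libraries, no variance trend, list means, other backgrounds and leaving out each library. Averaging replicates 3 and 4 into 1 library was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.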

Results

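The data describe gene expression in sorted, insulin reporter-positive cells made from primary mouse gallbladder cells, in 4 libraries of 1 group (rGBC2). The series title frames the cells as beta-like cells, so the comparisons asked which parts of the pancreatic beta-cell programme were present, how they compared with genes of gallbladder epithelium in the same library, and which other hormones and cell types were represented. The estimated depth lay between 22.1 M and 32.8 M reads per library. Of 20377 genes, 11001 lay above 1 RPKM and 4423 below it in limma's moderated test with Benjamini-Hochberg adjustment, and 3458 were listed at 0 in every library. Counts of list members given here are over all genes tested, and those adjusted over the list alone were equal except where stated.

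The 4 delivered transcription factors were among the most abundant transcripts of the cells. Pdx1, a regulator of pancreas formation and insulin transcription, was measured at 3180 ± 829 RPKM (SD, n = 4). Neurog3, which starts endocrine differentiation, stood at 2092 ± 540 RPKM and Mafa, an activator of insulin transcription in mature beta cells, at 1977 ± 541 RPKM. Pax6, an islet and eye regulator, stood at 1663 ± 433 RPKM. Their transcripts map in mm9 to chromosome 5 from 148081706 to 148086725 (Pdx1), chromosome 10 from 61595837 to 61597511 (Neurog3), chromosome 15 from 75577272 to 75578352 (Mafa) and chromosome 2 from 105516601 to 105537226 (Pax6). Replicate 2 had the lowest Pdx1 (1948 RPKM), Neurog3 (1290 RPKM) and Mafa (1183 RPKM), whereas the lowest Pax6 value was in replicate 1 (1189 RPKM). The ratio of Pdx1 to Neurog3 was 1.52 ± 0.0116 (SD, n = 4) and that of Pdx1 to Mafa 1.61 ± 0.0355, while the ratio of Pdx1 to Pax6 was 3.14 in replicate 1 and 1.39 to 1.78 in replicates 2 to 4. These values combine delivered and endogenous transcripts.

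Both insulin genes were transcribed in every library. Ins2, on chromosome 7 from 149864560 to 149865613, was measured at 3221 ± 1438 RPKM (SD, n = 4) and Ins1, on chromosome 19 from 52338812 to 52339948, at 334 ± 201 RPKM. Both passed the test for a level above 1 RPKM (limma, adjusted p = 6.45e-06 for Ins2 and 1.19e-05 for Ins1). The cells had been sorted on a reporter under an Ins1 promoter. A level of insulin transcripts above 1 RPKM was thus selected for, and this test does not bear on the success of reprogramming. Replicate 1 was lowest for both genes, with 1091 RPKM of Ins2 against 3704 to 4240 RPKM in the other 3 libraries and 107 RPKM of Ins1 against 222 to 523 RPKM. Ins2 exceeded Ins1 in 4 of 4 libraries, by 3.35 ± 0.49 on the log2(RPKM + 1) scale (SD, n = 4), which is 10.2-fold. Ins1 and Ins2 are related in sequence. How many reads could match both was not measured, so their separate values are uncertain. The exact sign-flip permutation test gave p = 0.13 for this difference, the smallest value it can give, and 0.175 after adjustment over the 7 differences tested.

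Transcripts of other islet hormones were present in the same libraries as those of insulin. Each library pools many cells, so hormones made in the same cell cannot be told from a mixture of cells. Sst, which encodes the delta-cell hormone somatostatin, was measured at 3276 ± 3154 RPKM (SD, n = 4), Gcg, the alpha-cell hormone glucagon, at 617 ± 373 RPKM, and Ghrl, ghrelin, at 202 ± 200 RPKM. All 3 lay above 1 RPKM (limma, adjusted p = 6.01e-05, 3.94e-05 and 0.000698). Sst was at 664 and 460 RPKM in replicates 1 and 2 and at 5573 and 6409 RPKM in replicates 3 and 4, with ratios to Ins2 of 0.608, 0.124, 1.45 and 1.51 in replicates 1 to 4. Ppy, pancreatic polypeptide, with 0.598 ± 0.292 RPKM, and Pyy, peptide YY, listed at 0 in replicates 1, 2 and 4 and at 0.11 RPKM in replicate 3, lay below 1 RPKM (limma, adjusted p = 0.025 and 1.25e-06).

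Ins1 was below Sst in 4 of 4 libraries, with a mean difference of -2.70 ± 1.19 on the log2(RPKM + 1) scale, which is 6.51-fold (exact sign-flip permutation p = 0.13, n = 4). Against Ppy it was above in 4 of 4 libraries, by 7.47 ± 1.02 on the log2(RPKM + 1) scale (exact sign-flip permutation p = 0.13). Against Gcg it was above in 1 library only, with a mean difference of -0.73 ± 0.96, which is smaller than its SD over libraries (exact sign-flip permutation p = 0.25). It was -1.02 without replicate 1 and -0.28 without replicate 2. The sort selected cells with an active Ins1 promoter, so these differences of Ins1 from other hormones hold for the sorted cells only. Of the regulators of other islet cell types, 4 of 8 lay above 1 RPKM. They included Hhex, a delta-cell regulator, at 89.4 ± 14.4 RPKM and Ttr, a transport protein abundant in alpha cells, at 18.0 ± 2.19 RPKM (SD, n = 4), while Irx2, an alpha-cell regulator, lay below it at 0.363 ± 0.203 RPKM. Irx1, another, was also below, at 0.08, 0, 0.26 and 0.26 RPKM in replicates 1 to 4.

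**Figure D1:**
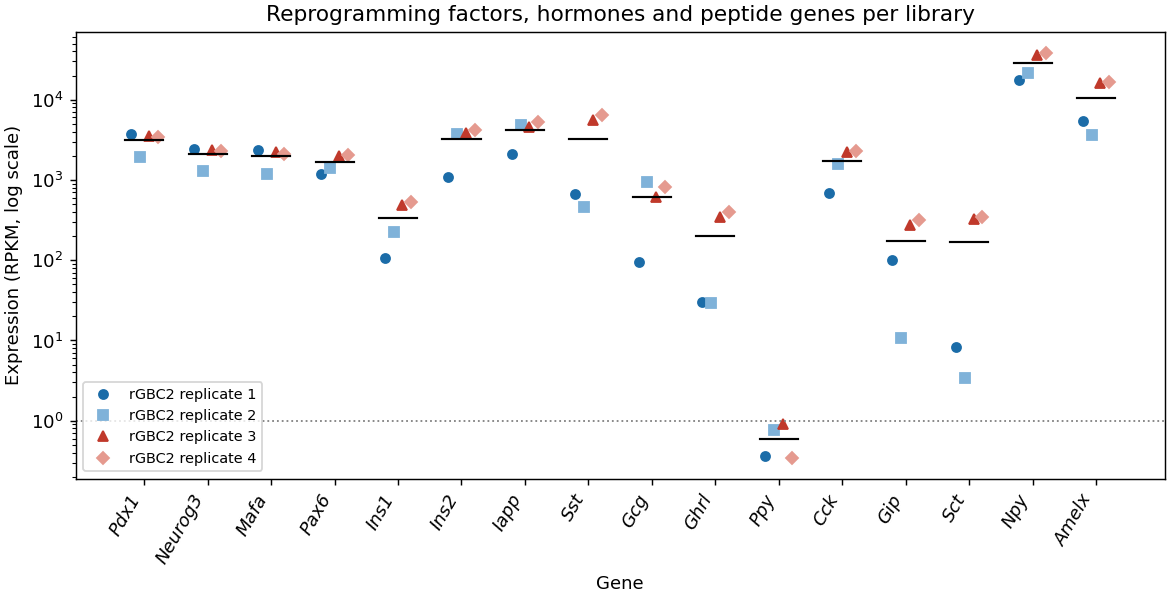
RPKM on a log axis of the 4 delivered factors and of hormone and peptide genes, with 1 symbol per rGBC2 library, a horizontal bar at the mean of the 4 and a dotted line at 1 RPKM. The factors lie between 1183 and 3739 RPKM in every library, Sst is at 460 to 664 RPKM in replicates 1 and 2 and at 5573 to 6409 RPKM in replicates 3 and 4, and Ppy is under 1 RPKM.

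Of 9 gut endocrine genes, 3 lay above 1 RPKM, and the median of 1.13 RPKM lay at percentile 8.61 of random lists. Cck, cholecystokinin, stood at 1714 ± 765 RPKM (SD, n = 4), Gip, the glucose-dependent insulinotropic peptide, at 176 ± 145 RPKM and Sct, secretin, at 169 ± 189 RPKM, and these were the 3 above. Sct was at 8.26 and 3.45 RPKM in replicates 1 and 2 and at 323 and 343 RPKM in replicates 3 and 4. Npy, neuropeptide Y, was the most abundant gene of every library at 28539 ± 10530 RPKM and took 3.61% to 6.64% of the summed RPKM. Of 12 genes of endocrine progenitors and immature beta cells, 6 lay above 1 RPKM, including Npy, Neurog3 and Cck, and 4 below it, including Pax4 with 0.19 ± 0.0766 RPKM and Aldh1a3 with 0.0975 ± 0.0465 RPKM. Neurog3 was delivered to the cells, so its place above 1 RPKM does not bear on the cell state. The list's median lay at percentile 25.45 of random lists.

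Genes for hormone processing and secretory granules lay above 1 RPKM in 14 of 16 cases, with a median of 28.0 RPKM, at percentile 99.5 of random lists, or 94.97 with only genes of at least 1 RPKM as background. Iapp, the islet amyloid peptide that is secreted with insulin, reached 4169 ± 1423 RPKM (SD, n = 4), Cpe, the carboxypeptidase that trims prohormones, 4034 ± 1048 RPKM and Ero1lb, an oxidoreductase for proinsulin folding, 633 ± 116 RPKM. Pcsk2, a prohormone convertase, lay above 1 RPKM, at 161, 104, 623 and 640 RPKM in replicates 1 to 4. Scg5, a chaperone of Pcsk2, was below 1 RPKM (limma, adjusted p = 0.023), at 0.59, 0, 0.5 and 0.83 RPKM in replicates 1 to 4. Pcsk1, another prohormone convertase, was at 0.1, 0, 1.95 and 1.67 RPKM and passed in neither direction (limma, adjusted p = 0.519). Chga, the granule protein chromogranin A, was at 33.1 and 23.7 RPKM in replicates 1 and 2 and at 471 and 470 RPKM in replicates 3 and 4. Of 14 genes of the exocytosis machinery, 12 lay above 1 RPKM, led by the synaptotagmin Syt13 with 536 ± 207 RPKM, Sytl4, a granule docking protein, with 128 ± 26.4 RPKM and Vamp2, a vesicle fusion protein, with 61.0 ± 9.31 RPKM. Syt4, which tunes calcium sensitivity of secretion in maturing beta cells, was below it, at 0.01 RPKM in 3 libraries and listed at 0 in replicate 2.

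Of 17 genes for glucose sensing and electrical excitability, 11 lay above 1 RPKM, 2 below, and 4 passed in neither direction, which is about the share above it among all genes tested. The list's median lay at percentile 44.6 of random lists, or at 2.36 with only genes of at least 1 RPKM as background. Abcc8, the regulatory subunit of the ATP-sensitive potassium channel, stood at 469 ± 112 RPKM (SD, n = 4) and Slc2a2, the glucose transporter GLUT2, at 120 ± 29.0 RPKM. Ucn3, a marker of mature beta cells, was at 0.14, 0, 0.03 and 0.08 RPKM in replicates 1 to 4 and Prlr, the prolactin receptor, at 0.0275 ± 0.00957 RPKM, both below 1 RPKM (limma, adjusted p = 2.23e-06 and 2.33e-07). The median of the processing and granule list exceeded that of this list in 4 of 4 libraries, by 2.04 ± 0.47 on the log2(RPKM + 1) scale (exact sign-flip permutation p = 0.13, n = 4).

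Islet transcription factors were transcribed in part. Of 18 measured factors, 10 lay above 1 RPKM, 3 below, and 5 passed in neither direction, and the list's median of 2.41 RPKM lay at percentile 12.0 of random lists, or at 0 with only genes of at least 1 RPKM as background. Insm1, a zinc finger regulator of endocrine cells, was highest at 151 ± 19.97 RPKM (SD, n = 4), followed by St18 at 48.3 ± 25.4 RPKM and Foxa2, a foregut and islet factor, at 33.1 ± 11.2 RPKM. Neurod1, a direct target of Neurog3, was at 9.64 ± 5.63 RPKM, and Isl1, a pan-endocrine factor, at 0.765 ± 0.478 RPKM, which passed in neither direction (limma, adjusted p = 0.227). Nkx6-1, a factor required for beta-cell identity, was at 0.02 and 0.03 RPKM in replicates 1 and 4, listed at 0 in replicates 2 and 3, and below 1 RPKM (limma, adjusted p = 2.33e-07). These values lie under that of 3 reads on a transcript of 1 kilobase in each library.

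**Figure D2:**
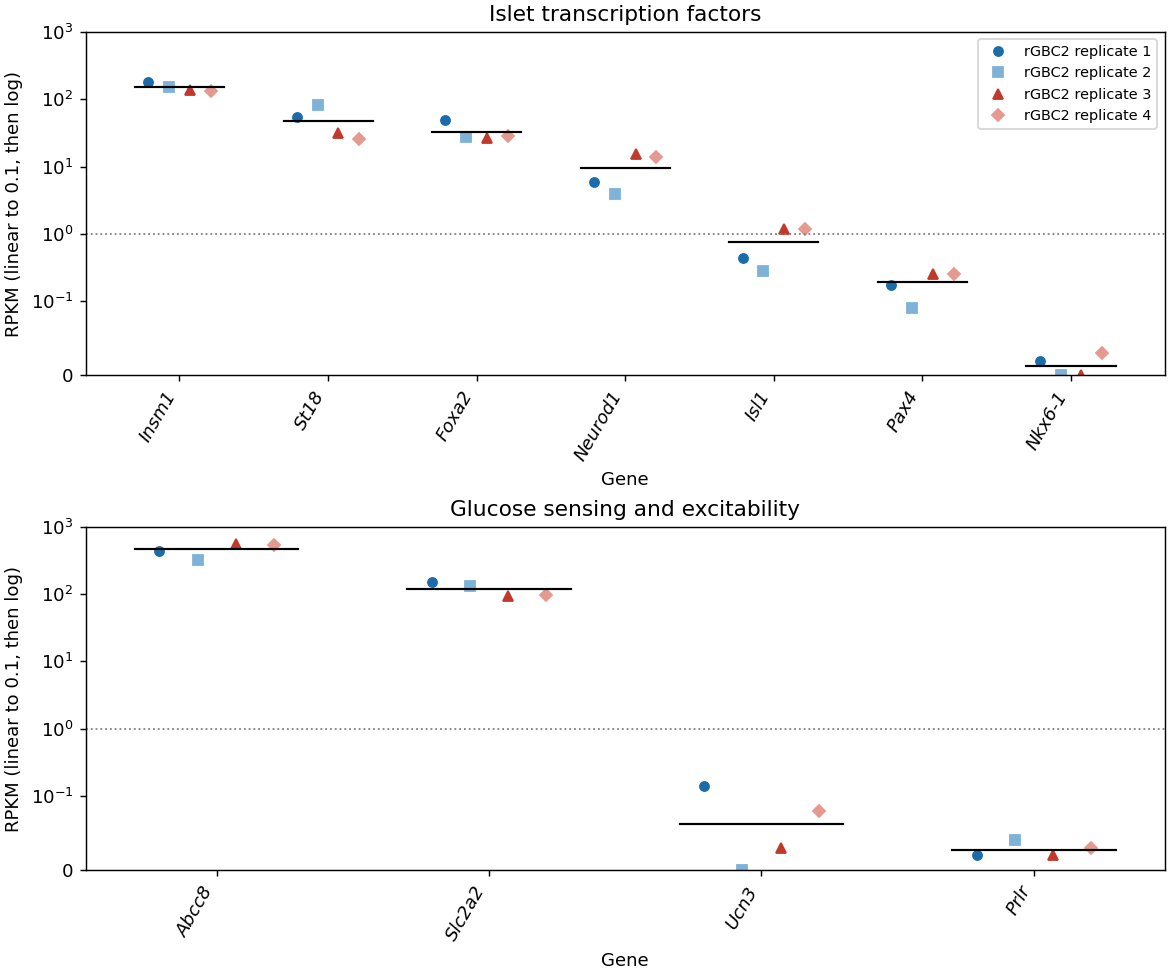
RPKM of the islet transcription factors (upper panel) and genes for glucose sensing and excitability (lower panel) that the text names, ordered by mean, with 1 symbol per rGBC2 library, a bar at the mean, a dotted line at 1 RPKM and an axis that is linear to 0.1 RPKM and logarithmic above. Insm1 and Abcc8 lead their lists at means of 151 and 469 RPKM, and Nkx6-1, Ucn3 and Prlr lie at the bottom, at 0.14 RPKM or less in every library.

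Genes of gallbladder and biliary epithelium were transcribed in the sorted cells. Of 33 measured genes, 22 lay above 1 RPKM, against 11001 of 16919 of all genes tested, 4 below, 6 in neither direction and 1 was listed at 0. Adjusted over the list alone, 20 lay above and 4 below, and the median of 17.1 RPKM lay at percentile 98.7 of random lists, or at 74.9 with only genes of at least 1 RPKM as background and at 94.1 without replicate 1. Spp1, the secreted phosphoprotein osteopontin of bile duct cells, stood at 639 ± 465 RPKM (SD, n = 4), Krt7, a ductal keratin, at 635 ± 186 RPKM and Prom1, a membrane protein of ductal progenitors, at 491 ± 362 RPKM. Replicate 2 had the highest Spp1 (1332 RPKM) and Prom1 (1029 RPKM), and without it their means were 408 and 311 RPKM. In the other 3 libraries Krt7 exceeded Spp1. Gpbar1, a bile acid receptor, lay below 1 RPKM at 0.118 ± 0.0842 RPKM.

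The median of the islet transcription factors was lower than that of the biliary list in 4 of 4 libraries, by a difference of -2.41 ± 0.48 on the log2(RPKM + 1) scale or 5.30-fold as a ratio of RPKM + 1, which understates differences of low genes (exact sign-flip permutation p = 0.13, n = 4). With the processing, granule, glucose-sensing and excitability genes added to these factors, the difference from the biliary list was -0.97 ± 1.37, smaller than its SD (exact sign-flip permutation p = 0.5). Its direction differed between libraries. It was -1.81 and -2.45 in replicates 1 and 2 and 0.25 and 0.15 in replicates 3 and 4. Replicates 1 and 2 also held reads of Y-linked genes and replicates 3 and 4 did not. Eif2s3y was at 48.5 and 44.7 RPKM in the former and listed at 0 in the latter. Across genes, the difference between these pairs of libraries also correlated with GC content (Spearman 0.610) and with transcript length (Spearman -0.266). Whether the change of direction rests on these trends was not tested.

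Genes reported as disallowed in beta cells, meaning genes that most tissues express and mature beta cells silence, lay above 1 RPKM in 13 of 18 cases, or 12 adjusted over the list alone. Their median of 10.1 RPKM lay at percentile 73.8 of random lists, or at 16.6 with only genes of at least 1 RPKM as background. Ldha, lactate dehydrogenase A, stood at 257 ± 71.2 RPKM (SD, n = 4), Cat, catalase, at 202 ± 101.2 RPKM and Mgst1, a microsomal glutathione transferase, at 178 ± 52.5 RPKM. Igfbp4 at 0.425 ± 0.0968 RPKM and Maf at 0.443 ± 0.166 RPKM were the 2 below it.

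Markers of cell types that a sort could carry over were mostly at or near 0, except those of the neuronal list. No endothelial gene of 10 lay above 1 RPKM and 8 lay below it, with Pecam1, an endothelial adhesion molecule, at 0.0975 ± 0.0435 RPKM (SD, n = 4) and the highest member, Esam, at 0.86 ± 0.169 RPKM. Of 18 hepatocyte genes, Apoa2 at 23.9 ± 10.0 RPKM and Alb, albumin, at 22.8 ± 14.3 RPKM lay above it and 11 below, including Apoa1 at 0.19 ± 0.197 RPKM, or 0.0933 RPKM without replicate 1. Alb was at 2.63 RPKM in replicate 1 and at 35.2 RPKM in replicate 4. Of 14 acinar genes, Cela1, an elastase, was the only one above, at 9.79 ± 1.998 RPKM, and Cpa1, a digestive carboxypeptidase, was listed at 0 in 3 libraries and at 0.26 RPKM in replicate 3.

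In the mesenchymal list 5 of 20 genes lay above 1 RPKM, led by Fn1, fibronectin, at 363 ± 121 RPKM, with Sparc at 0.43, 70.0, 13.9 and 14.9 RPKM in replicates 1 to 4 and Twist1 at 8.15 ± 5.62 RPKM, and 11 lay below it, including Col3a1, a fibrillar collagen, listed at 0 in 3 libraries and at 0.01 RPKM in replicate 4. Without replicate 2, Sparc had a mean of 9.74 RPKM and passed in neither direction, and Twist1 a mean of 5.42 RPKM. In the immune list Cd68, a lysosomal protein also made outside macrophages, stood at 138 ± 19.6 RPKM, C1qa at 15.0 ± 9.82 RPKM and Csf1r at 10.9 ± 6.56 RPKM, but Ptprc, the pan-leukocyte antigen CD45, was at 0.01 RPKM in replicates 1 and 2 and listed at 0 in the others, and Lyz2, a myeloid lysozyme, was at 0.113 ± 0.0785 RPKM. Of 8 smooth muscle genes, Myh11 at 10.3 ± 7.27 RPKM and Smtn at 10.3 ± 1.51 RPKM lay above 1 RPKM and 6 below. Of 13 neuronal genes, 8 lay above 1 RPKM, and the list's median lay at percentile 34.5 of random lists. Those above included Tubb3, a neuronal tubulin, at 139 ± 65.6 RPKM, Syp, synaptophysin, at 68.0 ± 45.0 RPKM and Nefl, a neurofilament subunit, at 61.9 ± 7.38 RPKM. Like many hormone and granule genes, Tubb3 and Syp were higher in replicates 3 and 4. Tubb3 was at 86.9, 76.8, 197 and 194 RPKM and Syp at 33.9, 24.45, 105 and 109 RPKM in replicates 1 to 4. Gap43, a growth cone protein, was at 0.075 ± 0.0332 RPKM and below 1 RPKM.

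**Figure D3:**
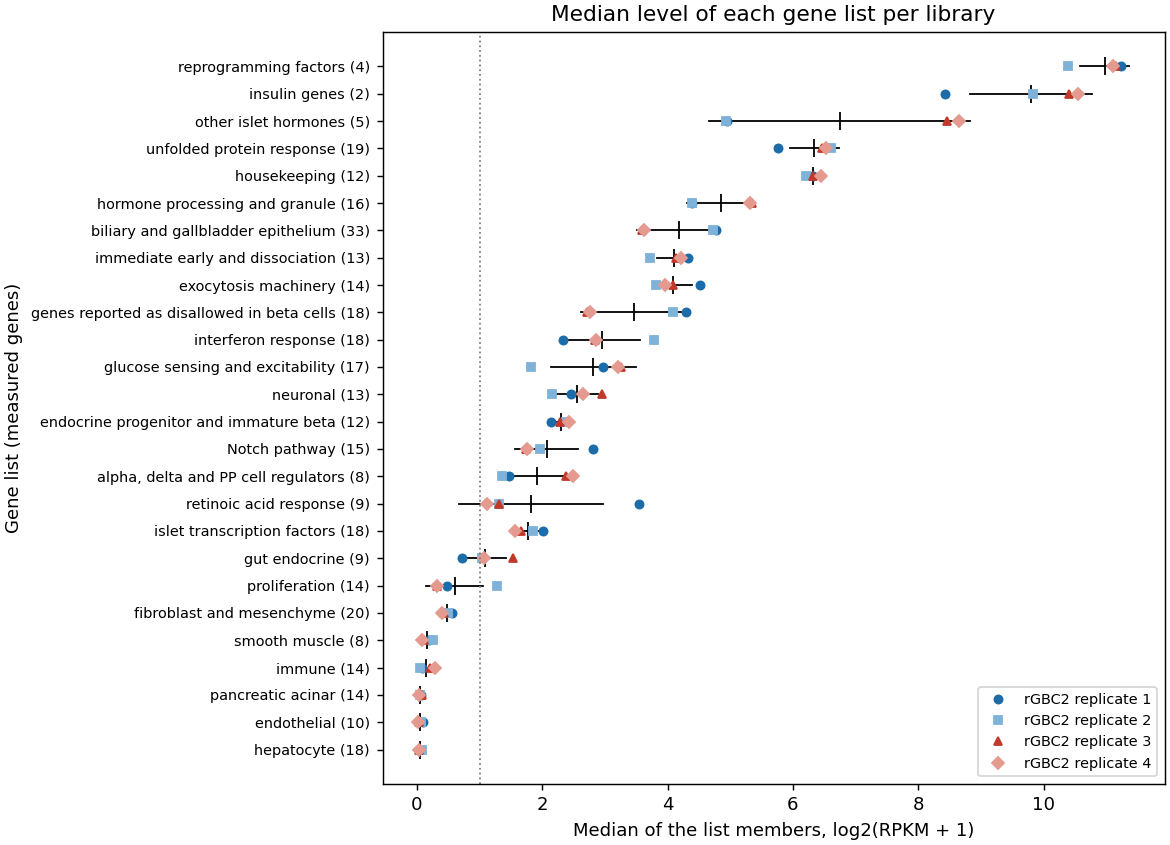
Median log2(RPKM + 1) of the members of each of the 26 gene lists, with the number of measured genes in brackets, 1 symbol per rGBC2 library, a vertical tick at the mean of the 4 libraries, a line of 1 SD to each side and a dotted line at 1 RPKM. Reprogramming factors and insulin genes lie highest, the biliary list lies above the islet transcription factors (means of 4.18 and 1.77), and hepatocyte, endothelial, acinar, immune and smooth muscle lists lie near 0.

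Genes of the unfolded protein response were all present, with 19 of 19 above 1 RPKM and a median of 80.2 RPKM. Hsp90b1, an endoplasmic reticulum chaperone, stood at 1188 ± 643 RPKM (SD, n = 4), Calr, calreticulin, at 850 ± 236 RPKM and Hspa5, the chaperone BiP, at 637 ± 136 RPKM. Interferon response genes lay above 1 RPKM in 13 of 18 cases, against 11001 of 16919 of all genes tested, and their median lay at percentile 46.4 of random lists. They were led by Bst2 with 211 ± 147 RPKM, Irf7 with 63.9 ± 23.0 RPKM and Rsad2 with 20.2 ± 20.4 RPKM, while Ifit3 and Cxcl10 lay below 1 RPKM. Without replicate 2 the means of Bst2 and Rsad2 were 138 and 10.1 RPKM. Immediate early genes lay above it in 11 of 13 cases, with Egr1 at 44.0 ± 18.3 RPKM, Jund at 37.8 ± 6.47 RPKM and Junb at 32.6 ± 4.33 RPKM.

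Cell cycle genes were low, with 3 of 14 above 1 RPKM and 6 below. Pcna, which also serves DNA repair, stood at 26.8 ± 9.55 RPKM, Mcm2 at 7.36 ± 1.10 RPKM and Ccna2 at 2.60 ± 0.910 RPKM, while Mki67, the proliferation antigen, was at 0.23 ± 0.394 RPKM (SD, n = 4), with 0.82 RPKM in replicate 2 and at most 0.05 RPKM in the others. Of 15 Notch pathway genes, 8 lay above 1 RPKM, led by Hes6 at 49.6 ± 17.8 RPKM, the ligand Dll1 at 43.3 ± 11.0 RPKM and the receptor Notch1 at 23.4 ± 9.11 RPKM. Hes5, a Notch target, at 0.21 ± 0.119 RPKM and the ligand Dll3 at 0.578 ± 0.291 RPKM lay below it. Of 9 retinoic acid response genes, 4 lay above it, including Tgm2 at 61.4 ± 8.44 RPKM and Dhrs3 at 9.39 ± 7.17 RPKM, or 5.99 RPKM without replicate 1, and Cyp26a1, a retinoic acid hydroxylase, was at 0.315 ± 0.118 RPKM. The medians of the Notch and retinoic acid lists lay at percentiles 25.1 and 20.7 of random lists.

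Among housekeeping genes, B2m at 1406 ± 564 RPKM, Eef1a1 at 938 ± 184 RPKM and Actb at 697 ± 149 RPKM (SD, n = 4) were high, and 10 of 12 lay above 1 RPKM. Gapdh, a glycolytic enzyme, was below it at 0.2, 0, 0.04 and 0.03 RPKM in replicates 1 to 4, and so was Ppia, a peptidyl-prolyl isomerase, at 0.138 ± 0.0873 RPKM. A value near 0 in this table is therefore reported as listed, not as absence of the transcript. The 15 most abundant genes, besides Npy, Pdx1, Neurog3, Mafa, Ins2, Sst, Iapp, Cpe and Cck, were Amelx at 10450 ± 6905 RPKM, Gnas at 4080 ± 352 RPKM, Gal at 3356 ± 1417 RPKM, Mt1 at 2749 ± 822 RPKM, Tff3 at 2728 ± 709 RPKM and Mt2 at 2139 ± 622 RPKM. Amelx encodes the enamel protein amelogenin, Gnas a stimulatory G protein subunit, Gal the neuropeptide galanin, Tff3 a mucosal trefoil peptide, and Mt1 and Mt2 metallothioneins.

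The 4 libraries were alike in rank across genes, with pairwise Spearman correlations from 0.953 to 0.995 over 16919 genes, which are not independent replicates. Replicates 3 and 4 were the closest pair. The SD of their log2 difference over 9482 genes with a mean of at least 5 RPKM was 0.159, against 0.541 for replicates 1 and 2 and 0.683 to 0.789 for the other pairs. Their median squared deviation was 2.47 times the counting variance, where counting error alone gives 0.455. This does not show whether they came from separate samples, and they were counted as 2 libraries as the labels give them. Of the 26 lists, 9 differed between libraries at percentile 95 or over of random lists of like level, among them lists of other kinds than hormone and secretory genes. The median SD of log2(RPKM + 1) was 1.53 for other islet hormones, 0.98 for processing and granule genes and 1.00 for the insulin genes, against 0.28, 0.32 and 0.40 in random lists of like level. Their spread lay at percentiles 100, 100 and 99.5, and without replicate 1 at 75.3 for the other islet hormones and 73.7 for the insulin genes. The other 6 were the biliary (99.99), interferon (99.99), gut endocrine (99.9), glucose-sensing (99.6), proliferation (99.1) and neuronal (97.7) lists, while the exocytosis list lay at 82.8. Without replicate 2 only the gut endocrine list of these 6 stayed at or over 95, with biliary at 89.1, neuronal at 42.9, proliferation at 13.3, glucose-sensing at 12.7 and interferon at 5.8. The genes with the largest SD were Sct, the Y-linked Eif2s3y, Ddx3y and Uty, Atp2a3, an intracellular calcium pump, Gpx3, a secreted glutathione peroxidase, Chga, Sparc, Pgcp and Gip, with SDs from 2.21 to 3.32.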

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

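The tests of random gene trios and of a common transcript were chosen after the result was seen. Gaps between libraries were taken on the log2(RPKM + 1) scale, so their shares of the range differ from those of the RPKM values printed beside them. In 19 of 110 groups of 4 values, 1 library stood far from the other 3, by a gap to the nearest library that exceeded the 95% critical value of Dixon's test as a share of the whole range, and chance gives this in about 1 of 20 groups of independent values. Replicates 3 and 4 were much closer to each other than the other pairs, so that replicate 1 or 2 stands apart more often than that rate, and the far library was 1 of these in each of the 19. Named genes with a mean under 1 RPKM were not tested in this way.

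Replicate 2 was the far library for Pdx1 (gap of 0.883 of the range), Neurog3 (0.883) and Mafa (0.835), at 1948, 1290 and 1183 RPKM against at least 3465, 2268 and 2129 RPKM in the others, and for the median of the 4 factors (0.837). It was also the far library for Atp2a3 (0.942), at 5.2 RPKM against 165 to 203 RPKM, for Tgm2 (0.901) and for Vamp2 (0.976), at 47 RPKM against 65.3 to 65.8 RPKM. In the other direction, Bst2 (0.911) was at 432 RPKM in replicate 2 against 130 to 145 RPKM and Rsad2 (0.903) at 50.8 RPKM against 9.39 to 11.1 RPKM, and the medians of the proliferation (0.83) and hepatocyte (0.855) lists were highest there.

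Replicate 1 was the far library for Ins2 (0.9), at 1091 RPKM against 3704 to 4240 RPKM, and for Iapp (0.849), at 2075 RPKM against 4529 to 5201 RPKM. The same library was low for Mt2 (0.859), for Pgcp (0.862), at 1.32 RPKM against 42.7 to 68.9 RPKM, and for the median of the unfolded protein response (0.835). It was high for Cd68 (0.885), for Foxa2 (0.881), at 49.9 RPKM against 26.6 to 28.7 RPKM, and for the median of the retinoic acid list (0.921).

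Pdx1, Neurog3 and Mafa kept nearly 1 ratio to each other in the 4 libraries, with a largest SD of their pairwise log2 ratios of 0.0398, whereas the SD of their log2 ratios to Pax6 was 0.50 to 0.54. Much of the latter rests on replicate 1, where the ratio of Pdx1 to Pax6 was 3.14, against 1.39, 1.78 and 1.69 in replicates 2 to 4. Of 10000 random trios from the 197 others of the 200 most abundant genes, 0% had a largest SD as small, and their median was 0.587, which argues against a property of abundant genes in general. A candidate explanation is that the 3 are read from 1 common transcript or vector that does not carry Pax6. The bounds set for it were met, but they restate the pattern that prompted them, so the test cannot decide this. The labels do not describe the vectors, no biological explanation was tested, and the pattern was found and tested on the same data.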

How the results depend on the processing

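The averaging of replicates 3 and 4 into 1 library was chosen after seeing the data, and the other alternatives before the data were examined. No difference between lists or genes changed direction in its mean under any alternative run, and with 3 or 4 libraries none could pass 0.05. The beta-cell lists minus the biliary list gave -1.37 to -0.47 when each library was left out. Genes above 1 RPKM numbered 10788 to 11066. Genes below 1 RPKM fell from 4423 to 1889 when only genes with a mean of at least 0.1 RPKM were tested, since fewer low genes were then tested, and otherwise numbered 4120 to 4460. At a threshold of 0.5 RPKM, 11841 lay above and 3621 below it. The lowest Spearman correlation between libraries was 0.901 over genes with a mean of at least 1 RPKM, against 0.953 over all genes not at 0 in every library. The number of lists with a spread at or over percentile 95 was 9, with a range of 5 to 10 when each library was left out, and 5 without replicate 2. Without that library the percentile was 5.8 for the interferon, 12.7 for the glucose sensing and 13.3 for the proliferation, 42.9 for the neuronal and 89.1 for the biliary list, and without replicate 1 it was 73.7 for the insulin genes and 75.3 for the other islet hormones. Over all lists and alternatives, 20 of 364 percentiles changed side of 95. With replicates 3 and 4 as 1 library, the number above 1 RPKM was 9 for islet transcription factors, 23 for biliary, 7 for neuronal, 12 for disallowed, 12 for interferon and 4 for mesenchymal genes, with 10 mesenchymal genes below it. Of the genes named except Pcsk2 and the ribosomal protein genes, read for each gene after seeing the data, Sparc and Gpx3 passed in neither direction in 5 of 10 alternatives at a threshold of 1 RPKM, Ppy in 3, Scg5 and Dll3 in 2 each and Npy in 1, without replicate 2, and none passed in the opposite direction. The mean of Npy without replicate 2 was 30789 RPKM. In the main test the variance trend gave Npy a standard error of 2.76, against an SD of 0.562 between libraries on the log2 scale. Its call therefore follows the trend more than its own spread. No paired analysis was possible because the series has 1 group and no other group to pair by number, while the 7 planned differences are paired within each library. Depth limits statements on values under about 0.135 RPKM for a transcript of 1 kilobase.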

Other observations

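Of the tests in this part, those of dilution and of different animals or cultures were chosen after the result was seen. Those of the length and base composition trend and of shared reads were written before the tested quantity was computed, although the values of the lists and of Gapdh and Ppia had been seen.

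Amelx, the second most abundant gene by its mean over the 4 libraries, lies on the minus strand of chromosome X from 165614045 to 165625141, within the span of Arhgap6 on the plus strand (165474560 to 165742367). Amelx was at 5403 and 3612 RPKM in replicates 1 and 2 and at 16099 and 16687 RPKM in replicates 3 and 4. In replicate 2 Iapp exceeded it at 4871 RPKM. Arhgap6 was at 1.73 ± 1.42 RPKM (SD, n = 4), or 1.04 RPKM without replicate 1. The use of strand in counting is not given in the sources used here.

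Hormone and granule genes with a mean of at least 5 RPKM were higher in the mean of replicates 3 and 4 than in that of replicates 1 and 2, although Gcg and Ero1lb were highest in replicate 2, and replicates 3 and 4 lacked reads of the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y. Over the 21 such members of the insulin, granule, other islet hormone and gut endocrine lists, 21 of them higher, the median difference of log2(RPKM + 1) was 1.75. It was 1.94 (95% bootstrap interval over members 1.44 to 2.65) after trends on transcript length and base composition were removed. The interval resamples genes, which are not independent, and does not measure the spread between libraries. Within these 4 libraries the value argues against these trends as the whole cause. Of all 32 measured members 29 were higher and 2 lower before removal, a count chosen after the data were seen. The trends were present across 9400 genes, with a Spearman correlation of the difference of 0.610 with GC content and of -0.266 with transcript length. Dilution by hormone-negative cells, which the sort on the insulin reporter should remove, would move all hormone genes alike. The SD between the 8 hormone genes with a mean of at least 5 RPKM was 1.756 times its error, between the bounds of 1 and 2 set for it. Reading values between these bounds as open was settled after this value was seen. Dilution alone would also leave ratios to Ins2 unchanged. The ratio of Sct was 0.00757, 0.000931, 0.0839 and 0.0809 in replicates 1 to 4. Those of Sst, Ghrl and Ins1 were also lower in replicates 1 and 2 than in replicates 3 and 4. Those of Cck, Gcg and Gip were not lower in both. These ratios were compared after the data were seen. The Y-linked genes were at 8.16 to 48.5 RPKM in replicates 1 and 2 and listed at 0 in replicates 3 and 4. The pairs thus differed in the presence of cells with a Y chromosome, and sex cannot be separated from the pair. Whether different animals or cultures caused the endocrine difference stays open. The count of Y-linked genes over 1 RPKM in both pairs was 0, but the pairs were defined by these genes, so it does not decide this. No biological explanation was tested.

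Gapdh and Ppia were listed under 1 RPKM, as were 18 of 82 ribosomal protein genes. A candidate explanation is that reads shared with near-identical copies were not counted, and no biological explanation was tested. Among the ribosomal protein genes the level fell with the share of 50-base words found in other genes (Spearman -0.296 across genes, which are not independent, permutation p = 0.00747). Of the words of Gapdh 82.5% were shared and of those of Ppia 40.5%, so the bound of 0.8 set for both transcripts was met by Gapdh alone, and the ribosomal genes carry the result. Single genes went both ways. Rps27 with 98.6% shared was at 0.19 RPKM, but Rps18 with 86.7% was at 91.8 RPKM and Rpl28 with 34.5% at 0.37 RPKM. Eef1a1, with 59.2% shared, was at 938 RPKM, although its unshared words could still be counted. The share of words is therefore not the whole account of the levels.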
